A study of Mus musculus with 16 samples.

How the data were processed

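RNA sequencing libraries of 16 samples were used: CD45-positive, LSK-enriched bone marrow cells of WT and Tet2-deficient mice aged 3 to 4 months, both sexes, in physioxia (3% oxygen) or after 6 hours in ambient air (about 21% oxygen), 4 replicates per group. A general protocol in the labels gives a range of air exposure, and the RNA protocol gives 6 hours. The labels state an RNA integrity number over 7, a low-input library kit, paired-end Illumina sequencing and about 30 M reads per sample. The deposited file, whose name gives DESeq2-normalized counts, holds a signal made by the authors: read counts per gene divided by 1 size factor per library. Each value was a whole multiple of the value of 1 read within 0.01 (100% of values), so whole reads were recovered. Upstream, per the submitters' processing notes, FastQC, cutadapt, STAR, HTSeq, DESeq2 and GRCm38 were named, with no versions or roles.

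The table held 6288 genes of 55536 in the GENCODE M21 annotation (22028 of these protein-coding), in 4 runs of ascending identifier of 1424, 2696, 1516 and 652 genes. How its genes were chosen is not stated. For 99.97% of them the smallest p of the 4 pairwise DESeq2 comparisons was under 0.05, for 99.43% under 0.02, and the largest was 0.0778. An adjustment over this table is lenient, so each count was also computed with every annotated gene, or every annotated protein-coding gene, outside the table counted as unchanged, a bound added after the data were seen. Backgrounds of list tests are likewise chosen genes. Symbols were matched by identifier for 6278 genes, and 10 had none. Always-named genes not analysed here, since the table lacks them, were Tet3, Dnmt3a, Vegfa, Bnip3, Ldha, Txnip, Cdkn1a, Ly6a and Flt3.

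Genes with a normalized count of at least 10 in at least 4 libraries were tested (6110 genes, 178 left out). The log2 of the normalized count plus 1 was fitted with limma 3.58.1 (R 4.3.3) with an intensity trend, all 16 libraries in 1 fit with a mean per group and no covariate, two-sided, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Contrasts were physioxia minus air in each genotype, Tet2-deficient minus WT in each oxygen condition, their interaction and both averages. The groups, contrasts, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Errors are SD over replicates for levels and SE of the fit for log2 differences. The table held 7.77 to 15.7 M reads per library, and the 10 most abundant genes took 12.3% to 20.3% of them. A ratio against 1 to 3 reads is that of the summed reads of the 2 groups, scaled by their summed size factors, given with a 95% counting interval, and a group at 0 with a floor of 3 reads per library.

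The genes named were, per oxygen and genotype contrast, up to 8 in each direction with the largest log2 difference among those past the threshold, with a mean of at least 50 and groups that did not overlap. Immunoglobulin and T cell receptor segments and symbols of the forms Gm plus digits, ending in Rik, or ENSMUSG identifiers were left out. Clone names such as AC102496.1 were kept. Where fewer than 3 passed, the 3 with the smallest p were named, and for the interaction the 5 per direction. A fixed set (among them Tet2, Tet1, Hif1a, Slc2a1, Pdk1, Fos, Jun, Egr1, Dusp1, Kit and Procr) was always named, with up to 4 members of each list described, by p. Hbb-bs was named after its values were seen. A few genes that the rule names are not reported here.

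Lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the 30 lists tested per contrast, and again with a correlation estimated per list. Counts of members are given over all tested genes and adjusted over the list alone. They cover only members in the table, which lacked many. It held 6 of 63 listed ribosomal protein genes and 6 of 52 of nuclear oxidative phosphorylation. It held 15 of 40 HIF and glycolysis genes and 23 of 37 long-term stem cell genes. Such counts do not describe whole pathways. The 31 lists were HIF targets and glycolysis, AP-1 and immediate early genes, TNF and NF-kB response, heat shock and unfolded protein, ATF4 integrated stress response, antioxidant and NRF2 targets, p53 targets, interferon response, long-term stem cell genes, lymphoid priming, myeloid progenitor granule genes, erythroid progenitor genes, megakaryocyte and platelet genes, mature neutrophil markers, monocyte and macrophage markers, B cell markers, T and NK cell markers, dendritic cell markers, basophil, mast cell and eosinophil markers, stromal and endothelial markers, S phase, G2/M phase, nuclear oxidative phosphorylation, mitochondrially encoded genes, cytosolic ribosomal proteins, cholesterol synthesis, DNA methylation and oxygen-dependent dioxygenases, Hox and self-renewal regulators, cytokine and JAK/STAT signalling, replication-dependent histones, and sex-linked genes, of which 2 were measured and not tested as a list.

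The labels say that enriched cells were divided between the oxygen conditions and that replicates were matched, but not that the replicate number marks the animal. As a check, each library's deviations from its group mean were correlated across genes between groups. In WT each number went best with itself (r = 0.332, 0.178, 0.162 and 0.331 for numbers 1 to 4). In Tet2-deficient cells number 1 alone did (r = 0.322, −0.275, 0.042 and −0.006), and across genotypes none did. The replicate block was therefore an alternative. For the genotype contrasts it joined WT and Tet2-deficient libraries of the same number, for which the check showed no pairing. No pair of libraries was a duplicate (0 identical, smallest chi-square per degree of freedom within a group 14.9).

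Alternatives were a pseudocount of 0.5 or 10, no filter or a minimum of 50, TMM factors or quantile normalization, the replicate block, a fit of the contrast's groups alone, robust empirical Bayes, array quality weights, edgeR 4.0.16 and DESeq2 1.42.0 on whole reads, an absolute log2 difference of at least 1, fry for lists, and each library left out in turn. Added after the data were seen were fits without Tet2-deficient air 3 and 4, and without Tet2-deficient air 3 and physioxia 2. On simulated WT libraries with 200 changed genes, limma recovered 22.4%, 67.2% and 90.9% of changes of 1.5-fold, 2-fold and 4-fold with 5 false calls, edgeR 22.4%, 67.2% and 89.4% with 4, and DESeq2 35.8%, 76.1% and 97.0% with 26. With no changed gene they called 0, 0 and 5. Camera gave 2 of 100 unchanged lists a p under 0.05. The simulated genes were drawn independently of each other, whereas the correlation estimated for the erythroid list was 0.81. The simulation thus does not show how camera with the preset correlation errs on correlated lists. Figures were drawn with Python 3.11.15, matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.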

Results

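Gene expression was measured by bulk RNA sequencing in CD45-positive mouse bone marrow cells enriched for the lineage-negative, Kit-positive, Sca1-positive (LSK) fraction, which holds haematopoietic stem cells and multipotent progenitors. Marrow of wild-type (WT) and Tet2-deficient mice was harvested in a chamber at 3% oxygen, called physioxia here. The enriched cells either stayed there or were moved to ambient air, about 21% oxygen, for 6 hours before RNA extraction. The 16 libraries fell into 4 groups of 4 replicates: WT air, Tet2-deficient air, WT physioxia and Tet2-deficient physioxia. The table used here held 6288 genes. Its reads per library, in replicate order, came to 12.1, 11.6, 10.6 and 12.3 M in WT air and 13.0, 12.5, 10.997 and 12.7 M in Tet2-deficient air. They came to 10.4, 15.7, 12.3 and 14.2 M in WT physioxia and 9.09, 9.99, 7.77 and 12.8 M in Tet2-deficient physioxia. Of these genes, 99.97% had an unadjusted DESeq2 p under 0.05 in at least 1 of the 4 pairwise comparisons, so shares of called genes describe genes already chosen for a difference, not the transcriptome.

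Tet2, a dioxygenase that oxidises methylated cytosine in DNA, was lower in the Tet2-deficient libraries but still detected in each. The normalized count of Tet2 (ENSMUSG00000040943, GRCm38 chromosome 3, 133463679 to 133545139) was 855 ± 157 in WT air and 554 ± 54.1 in Tet2-deficient air (mean ± SD, n = 4 per group, as for all such values below). In physioxia it was 731 ± 97.4 in WT and 482 ± 36.0 in Tet2-deficient cells. Per library, in replicate order, the counts were 993, 650, 962 and 813 in WT air, 782, 592, 812 and 739 in WT physioxia, 626, 564, 519 and 506 in Tet2-deficient air, and 489, 447, 463 and 530 in Tet2-deficient physioxia. The highest Tet2-deficient library (626, in air) thus lay above the lowest WT library (592, in physioxia), but within each oxygen condition the genotypes did not overlap. The log2 difference between the genotypes was −0.61 ± 0.14 in air (± SE, as for all log2 differences below; limma adjusted p = 0.00223) and −0.59 ± 0.14 in physioxia (adjusted p = 0.00267). Between physioxia and air it was −0.22 ± 0.14 in WT (adjusted p = 0.443) and −0.20 ± 0.14 in Tet2-deficient cells (adjusted p = 1.0), neither past the test. A count over the whole gene includes exons outside any deleted part, so these levels check the genotype labels only in part.

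In air, most of the measured immediate early, long-term stem cell and erythroid progenitor genes were higher in Tet2-deficient than in WT LSK-enriched cells, and most of the measured TNF and NF-kB response genes and neutrophil markers were lower. No list kept its call with an estimated correlation (smallest adjusted p = 0.295 with an estimated correlation). Fos, an AP-1 transcription factor subunit (chromosome 12, 85473890 to 85477273), stood at 24887 ± 976 against 5430 ± 2052 (2.28 ± 0.29, adjusted p = 1.55e-05). Klf1, the master regulator of erythroid genes (chromosome 8, 84901928 to 84905291), stood at 6936 ± 3297 against 1194 ± 347 (2.47 ± 0.35, adjusted p = 4.21e-05). Vcam1, an adhesion molecule of marrow macrophages and stroma (chromosome 3, 116109949 to 116129688), stood at 1010 ± 147 against 4235 ± 400 (−2.07 ± 0.15, adjusted p = 4.78e-08). Il6, an inflammatory cytokine, stood at 20 ± 6.84 against 106 ± 15.2 (−2.42 ± 0.28, adjusted p = 6.61e-06).

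Among stimulus-response genes in air, 18 of the 21 AP-1 and immediate early genes measured were higher and 3 lower, with the same numbers adjusted over the list alone (median 0.94, camera adjusted p = 0.00258, adjusted p = 0.44 with an estimated correlation). They included Btg2, an antiproliferative gene (1.37 ± 0.13), the transcription factors Egr1 (2.51 ± 0.35) and Myc (0.78 ± 0.11), Jun (0.77 ± 0.19) and the MAP kinase phosphatase Dusp1 (2.11 ± 0.30). Of 19 TNF and NF-kB response genes, 1 was higher and 16 lower, with the same numbers adjusted over the list alone (median −1.18, camera adjusted p = 3.68e-05, adjusted p = 0.44 with an estimated correlation). Birc3, an inhibitor of apoptosis (−1.51 ± 0.16), and Traf1, a TNF receptor adaptor (−2.04 ± 0.26), were among those lower. Of 21 interferon response genes, 3 were higher and 13 lower, with the same numbers adjusted over the list alone (median −0.60, camera adjusted p = 0.0121, adjusted p = 0.44 with an estimated correlation). The antiviral gene Rsad2 (−2.90 ± 0.28) and the chemokine Cxcl10 (−1.89 ± 0.21) were lower, and Gbp7, a guanylate-binding protein, was higher (1.04 ± 0.11). Of 14 heat shock and unfolded protein genes, 1 was higher and 12 lower, with the same numbers adjusted over the list alone (median −0.52, camera adjusted p = 0.0242, adjusted p = 0.44 with an estimated correlation). Xbp1 (−1.04 ± 0.14), Manf (−0.63 ± 0.14) and Bag3 (−1.04 ± 0.23) were among those lower. Of 10 targets of ATF4, the transcription factor of the integrated stress response, 2 were higher and 7 lower, with the same numbers adjusted over the list alone (median −0.79, camera adjusted p = 0.0434, adjusted p = 0.44 with an estimated correlation). Trib3 (−2.06 ± 0.27) and Chac1 (−2.38 ± 0.32) had the smallest p. The heat shock and ATF4 lists did not pass after quantile normalization (adjusted p = 0.186 and adjusted p = 0.122), nor without Tet2-deficient air libraries 3 and 4 (adjusted p = 0.129 and adjusted p = 0.0694), and the ATF4 list did not with a minimum count of 50 (adjusted p = 0.0527).

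Stem cell and lineage genes also lay apart in air. Of 23 long-term stem cell genes, 21 were higher and 0 lower, with the same numbers adjusted over the list alone (median 0.98, camera adjusted p = 3.68e-05, adjusted p = 0.295 with an estimated correlation). Pdzk1ip1 (1.38 ± 0.18), Gfi1b, a repressor needed for erythroid and megakaryocyte development (1.38 ± 0.18), Mllt3, a regulator of stem cell maintenance (1.27 ± 0.19), and Ndn (2.25 ± 0.36) had the smallest p. The stem cell surface protein Procr (0.97 ± 0.17) and the stem cell factor receptor Kit (0.71 ± 0.18) were higher as well. Of 25 erythroid progenitor genes, 24 were higher and 0 lower, with the same numbers adjusted over the list alone (median 2.08, camera adjusted p = 7.02e-06, adjusted p = 0.44 with an estimated correlation). Ermap (2.49 ± 0.36) and the carbonic anhydrases Car1 (2.25 ± 0.34) and Car2 (1.89 ± 0.27) were among them. The mean log2 level of 22 erythroid genes without the globins was 11.1, 11.2, 12.7 and 11.8 in Tet2-deficient air replicates 1 to 4 against 9.27 to 10.1 in WT air. Of 12 Hox and self-renewal regulators, 9 were higher and 1 lower, with the same numbers adjusted over the list alone (median 0.93, camera adjusted p = 0.0259, adjusted p = 0.44 with an estimated correlation), among them Tal1 (2.33 ± 0.38) and Hmga2 (1.45 ± 0.25). Of 16 S phase genes, 14 were higher and 0 lower, with the same numbers adjusted over the list alone (median 0.52, camera adjusted p = 0.00979, adjusted p = 0.44 with an estimated correlation), among them Ccne1, which encodes cyclin E (3.32 ± 0.52), and E2f8 (1.04 ± 0.26). E2f8 did not pass without Tet2-deficient air libraries 3 and 4 (adjusted p = 0.0642). The S phase list stood at 11.4, 11.5, 12.1 and 11.8 in mean log2 in Tet2-deficient air replicates 1 to 4, highest in replicates 3 and 4 as the erythroid genes were.

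Neutrophil, monocyte, basophil and T cell marker lists passed in air with negative medians, while B cell, dendritic cell and megakaryocyte lists did not pass by camera. By fry, which tests a list without setting it against other genes, the B cell (adjusted p = 0.00187) and dendritic cell (adjusted p = 0.0495) lists passed, as did the HIF and glycolysis list (adjusted p = 0.00187). By camera with an estimated correlation these lay at adjusted p = 0.44, adjusted p = 0.653 and adjusted p = 0.44. WT air replicates 1 to 4 lay at 10.33, 10.27, 9.44 and 9.36 in mean log2 on the monocyte list, against 9.04 to 9.19 in Tet2-deficient air. On the T cell list they lay at 7.6, 7.1, 6.4 and 6.2, against 4.9 to 5.5. These gaps were thus widest for WT replicates 1 and 2. The neutrophil list fell in the same order in WT air, and the basophil list did not. Of 13 mature neutrophil markers, 0 were higher and 10 lower, with the same numbers adjusted over the list alone (median −2.10, camera adjusted p = 0.000896, adjusted p = 0.44 with an estimated correlation). They included Il1r2, a decoy interleukin receptor (−3.01 ± 0.34), and the granule proteins Ngp (−2.91 ± 0.39), Camp (−2.82 ± 0.40) and Lcn2 (−1.45 ± 0.26). Of 16 myeloid progenitor granule genes, 0 were higher and 11 lower, with the same numbers adjusted over the list alone (median −0.48, camera adjusted p = 0.00166, adjusted p = 0.44 with an estimated correlation), among them Fcgr3 (−1.31 ± 0.16) and Hk3 (−0.90 ± 0.14). Of 15 monocyte and macrophage markers, 2 were higher and 11 lower, with the same numbers adjusted over the list alone (median −0.77, camera adjusted p = 0.0173, adjusted p = 0.44 with an estimated correlation), with Ly86 (−1.81 ± 0.21) and Cd68 (−0.76 ± 0.15) among them. Of 21 basophil, mast cell and eosinophil markers, 2 were higher and 15 lower (3 and 15 adjusted over the list alone) (median −1.28, camera adjusted p = 3.68e-05, adjusted p = 0.295 with an estimated correlation). The basophil proteases Prss34 (−3.14 ± 0.27) and Mcpt8 (−1.54 ± 0.17) and the receptor chains Il5ra (−2.45 ± 0.21) and Ms4a2 (−1.57 ± 0.17) had the smallest p. Of 24 T and NK cell markers, 1 was higher and 19 lower (1 and 20 adjusted over the list alone) (median −1.67, camera adjusted p = 0.00105, adjusted p = 0.44 with an estimated correlation), among them Ccl5 (−2.36 ± 0.44), Cd3e (−2.60 ± 0.55) and Lef1 (−2.70 ± 0.61), and the gene higher over all genes was Cd4 (2.08 ± 0.35). Of 11 replication-dependent histone genes, 1 was higher and 7 lower, with the same numbers adjusted over the list alone (median −0.71, camera adjusted p = 0.0403, adjusted p = 0.44 with an estimated correlation), among them Hist1h2bj (−2.14 ± 0.23) and Hist1h2bc (−1.49 ± 0.18).

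Genes of glycolysis and of the hypoxia-inducible factor HIF did not pass as a list in air (median −0.38, camera adjusted p = 0.149). Of 15 measured, 4 were higher and 9 lower (4 and 10 adjusted over the list alone). Hif1a itself (−0.97 ± 0.16), the glucose transporter gene Slc2a1 (−0.77 ± 0.20) and the glycolytic genes Pfkp (−1.21 ± 0.16) and Gapdh (−0.69 ± 0.10) were lower, with Mxi1 (−0.79 ± 0.12) and Bhlhe40 (−1.46 ± 0.26). Pdk1, which inhibits pyruvate dehydrogenase, was higher (0.61 ± 0.13), as was Tet1, a relative of Tet2 (0.83 ± 0.19). Slc2a1 did not pass without Tet2-deficient air libraries 3 and 4 (adjusted p = 0.087).

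The largest differences in air included genes nearly absent from 1 genotype. Gbp2b, which encodes a guanylate-binding protein (chromosome 3, 142594847 to 142619179), had 1785 reads in the 4 Tet2-deficient air libraries and 1 read in WT air, a ratio of summed reads, scaled by the summed size factors of each group, of 1563 with a 95% counting interval of 280.1 to 61760. Atp6v0e2, a proton pump subunit, had 1340 reads against 2 (ratio by the same measure 587, interval 162 to 4849), and the pseudogene Ear-ps2 821 reads against 3 (ratio 240, interval 81.7 to 1164). Rps13-ps1 (6.63 ± 0.35), Ear10 (5.88 ± 0.37), Prss41 (5.74 ± 0.72), Ttll11 (5.38 ± 0.44) and Atp6v0c-ps2 (5.20 ± 0.16) followed. The noncoding gene AC102496.1 had 0 reads in all 4 Tet2-deficient air libraries and was at least 94.7-fold lower than in WT air, taking 3 reads per library as the floor. Baiap3 had 1 read against 864 in WT air (ratio 987, interval 177 to 39020). Fgf3, a fibroblast growth factor (−5.92 ± 0.51), Eps8l1 (−5.86 ± 0.46), Zfp125 (−5.75 ± 0.47), Tnfaip6 (−4.75 ± 0.39) and the calcium sensors Kcnip3 (−4.67 ± 0.28) and Ncs1 (−4.48 ± 0.49) were also lower. These intervals and floors cover counting error only.

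Over all 6110 tested genes, limma called 2575 higher and 2283 lower in Tet2-deficient air libraries, 4858 in all. With the replicate number as a block the count was 4822, but no number went best with itself across genotypes, so this block models no shown pairing. With every annotated gene outside the table counted as unchanged it was 2432, and without Tet2-deficient air libraries 3 and 4 it was 2760, against 3348 to 4199 without the other pairs of Tet2-deficient air libraries. Quantile normalization moved the median log2 difference of all genes by −0.12, to 0.12, and turned the balance of calls, to 1984 higher and 2303 lower.

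**Figure D1:**
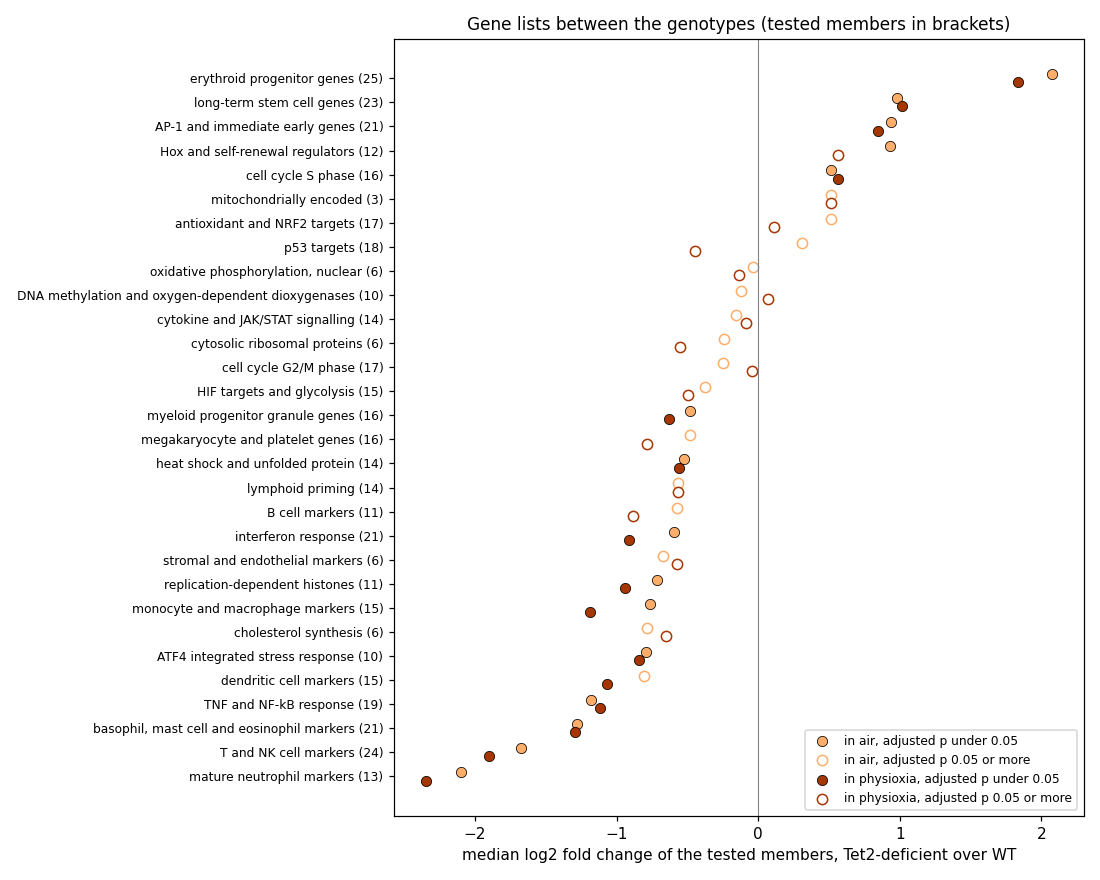
Median log2 difference between Tet2-deficient and WT libraries for each tested gene list, in air and in physioxia, filled where the camera adjusted p was under 0.05, with the number of tested members in brackets. Erythroid progenitor genes lay highest in air (median 2.08) and mature neutrophil markers lowest (median −2.10).

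In physioxia, the same question was asked of cells kept at 3% oxygen. Fos stood at 24964 ± 6207 in Tet2-deficient against 4722 ± 2295 in WT libraries (2.48 ± 0.29, adjusted p = 6.73e-06) and Klf1 at 6747 ± 3084 against 1532 ± 767 (2.15 ± 0.35, adjusted p = 0.000145). Il6 stood at 12.3 ± 2.14 against 108 ± 25.2 (−3.03 ± 0.28, adjusted p = 6.33e-07) and Vcam1 at 1184 ± 230 against 3528 ± 682 (−1.57 ± 0.15, adjusted p = 9.6e-07). Of the AP-1 and immediate early genes, 13 were higher and 1 lower, with the same numbers adjusted over the list alone (median 0.84, camera adjusted p = 0.00719, adjusted p = 0.428 with an estimated correlation), with Btg2 (1.58 ± 0.13), Egr1 (2.14 ± 0.35), Nr4a1 (1.11 ± 0.18), Myc (0.86 ± 0.11), Dusp1 (1.83 ± 0.30) and Jun (0.67 ± 0.19) among them. Of the TNF and NF-kB response genes, 0 were higher and 16 lower, with the same numbers adjusted over the list alone (median −1.12, camera adjusted p = 2.22e-05, adjusted p = 0.426 with an estimated correlation), Cd83 (−2.12 ± 0.29) among them. Of the interferon response genes, 2 were higher and 15 lower, with the same numbers adjusted over the list alone (median −0.91, camera adjusted p = 0.00317, adjusted p = 0.444 with an estimated correlation). Among long-term stem cell genes, 20 were higher and 0 lower (21 and 0 adjusted over the list alone) (median 1.02, camera adjusted p = 8.44e-05, adjusted p = 0.254 with an estimated correlation), with Gfi1b (1.20 ± 0.18), Kit (1.04 ± 0.18), Mycn (1.02 ± 0.19) and Procr (0.61 ± 0.17) among them. In the erythroid list, 21 were higher and 0 lower, with the same numbers adjusted over the list alone (median 1.83, camera adjusted p = 2.22e-05, adjusted p = 0.45 with an estimated correlation), with the erythropoietin receptor gene Epor at 1.89 ± 0.32. Of the S phase genes, 11 were higher and 0 lower, with the same numbers adjusted over the list alone (median 0.56, camera adjusted p = 0.00919, adjusted p = 0.45 with an estimated correlation), with E2f8 (1.28 ± 0.26) and Exo1 (0.73 ± 0.15) among them.

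In physioxia, the neutrophil, monocyte, basophil, T cell and dendritic cell marker lists passed with negative medians, while B cell and megakaryocyte lists did not pass by camera but passed by fry (adjusted p = 8.01e-05 and adjusted p = 0.0215), as did the Hox and self-renewal (adjusted p = 0.000574) and HIF and glycolysis (adjusted p = 0.00145) lists. By camera with an estimated correlation these lay at adjusted p = 0.426, adjusted p = 0.531, adjusted p = 0.428 and adjusted p = 0.45. WT physioxia replicates 1 to 4 lay at 8.40, 8.12, 7.42 and 7.05 in mean log2 on the dendritic cell list, against 6.90 to 6.98 in Tet2-deficient physioxia. On the T cell list they lay at 7.90, 7.30, 6.44 and 5.98, against 4.74 to 5.55. The monocyte and neutrophil lists fell in the same order in WT physioxia, and the basophil list did not. Of the neutrophil markers, 0 were higher and 12 lower, with the same numbers adjusted over the list alone (median −2.35, camera adjusted p = 8.09e-05, adjusted p = 0.426 with an estimated correlation), and of the myeloid progenitor granule genes, 0 were higher and 16 lower, with the same numbers adjusted over the list alone (median −0.63, camera adjusted p = 0.000246, adjusted p = 0.428 with an estimated correlation). Among monocyte and macrophage markers, 1 was higher and 10 lower (1 and 12 adjusted over the list alone) (median −1.19, camera adjusted p = 0.00317, adjusted p = 0.428 with an estimated correlation). Among basophil, mast cell and eosinophil markers, 1 was higher and 16 lower, with the same numbers adjusted over the list alone (median −1.29, camera adjusted p = 2.22e-05, adjusted p = 0.254 with an estimated correlation). Of the T and NK cell markers, 1 was higher and 19 lower, with the same numbers adjusted over the list alone (median −1.90, camera adjusted p = 0.000251, adjusted p = 0.428 with an estimated correlation), with Tcf7 (−1.70 ± 0.33) among them. The 15 dendritic cell markers passed in physioxia, where 2 were higher and 11 lower, with the same numbers adjusted over the list alone (median −1.07, camera adjusted p = 0.0408, adjusted p = 0.531 with an estimated correlation). Among heat shock genes, 1 was higher and 10 lower, with the same numbers adjusted over the list alone (median −0.56, camera adjusted p = 0.0113, adjusted p = 0.447 with an estimated correlation), with Hspa8 at −0.82 ± 0.21. Among ATF4 targets, 1 was higher and 8 lower (2 and 8 adjusted over the list alone) (median −0.84, camera adjusted p = 0.0147, adjusted p = 0.426 with an estimated correlation), with Atf4 itself at −0.78 ± 0.11. Neither of these lists passed after quantile normalization (adjusted p = 0.246 and adjusted p = 0.0549). Among the histone genes, 1 was higher and 8 lower, with the same numbers adjusted over the list alone (median −0.94, camera adjusted p = 0.00842, adjusted p = 0.428 with an estimated correlation), with Hist1h4i at −1.30 ± 0.19. The Hox and self-renewal list did not pass (median 0.57, camera adjusted p = 0.133): 6 were higher and 1 lower (6 and 0 adjusted over the list alone). The HIF and glycolysis list did not pass either (median −0.49, camera adjusted p = 0.133): 4 were higher and 10 lower (5 and 10 adjusted over the list alone). Hif1a (−0.81 ± 0.16) and Slc2a1 (−0.59 ± 0.20) were lower and Pdk1 (0.47 ± 0.13) and Tet1 (1.41 ± 0.19) higher. Slc2a1 did not pass without WT library 4 (adjusted p = 0.0526) or without Tet2-deficient library 2 (adjusted p = 0.0611) or 3 (adjusted p = 0.0715) of this condition.

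The largest differences in physioxia were mostly those of air. Gbp2b had 1779 reads against 2 (ratio of summed reads scaled as above 1001, interval 276.7 to 8272), Ear-ps2 had 0 reads in all 4 WT libraries and was at least 61.4-fold higher in Tet2-deficient ones, and Atp6v0e2 had 914 reads against 4. AC102496.1 had 3 reads against 1028 (ratio 304.5, interval 104 to 1479) and Baiap3 4 reads against 805. The pseudogene AC115117.1 (5.26 ± 0.28) was among the 8 genes furthest above WT, and C5ar1, the receptor of complement fragment C5a (−4.37 ± 0.42), among the 8 furthest below. Of the tested genes, limma called 2192 higher and 2051 lower, 4243 in all, against 4203 with the replicate number as a block and 2477 with annotated genes outside the table counted as unchanged. As in air, that block models no shown pairing. After quantile normalization it called 1909 higher and 1938 lower. Across genes, which are not independent replicates, the genotype differences of both conditions correlated (Pearson r = 0.899). Of the called genes, 1775 were higher in both conditions and 1682 lower in both, against 924 and 766 for independent calls, and 1 was called in opposite directions. Neither this r nor the numbers for independent calls take account of how the table's genes were chosen. In run 2 of ascending identifier, 98.96% of tested genes were higher in Tet2-deficient libraries in air and 99.85% in physioxia. In run 3 these shares were 1.08% and 0.07%. The likeness of both conditions may thus come in part from that choice. Averaged over both conditions, limma called 2874 genes higher and 2575 lower, 5449 in all. That fit counted air and physioxia libraries as independent. The enriched cells were divided between these conditions, so the libraries may share animals and the count may be too high.

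In WT cells, keeping LSK-enriched cells at 3% oxygen was set against 6 hours in air. All WT air libraries came before all WT physioxia libraries in sample number, so oxygen and a batch along these numbers cannot be told apart. Within Tet2-deficient air, Eif3b stood at 2179 and 1934 in libraries 1 and 2 and at 21866 and 21308 in 3 and 4. It thus moved there without a change of oxygen. Eif3b, a subunit of a translation initiation factor (ENSMUSG00000056076, chromosome 5, 140419328 to 140443360), stood at 20623 ± 1501 in physioxia against 2352 ± 1411 in air (3.28 ± 0.64, adjusted p = 0.0113). Rab5if (chromosome 2, 156863128 to 156873563) stood at 4036 ± 2614 against 337 ± 274 (3.61 ± 0.58, adjusted p = 0.00955). Mir17hg, the host transcript of a microRNA cluster (chromosome 14, 115042879 to 115046727), stood at 25.5 ± 5.02 against 97.8 ± 21.8 (−1.89 ± 0.31, adjusted p = 0.00955). Of 40 listed HIF targets and glycolytic genes, which low oxygen is known to raise, 15 were measured. Vegfa, Bnip3 and Ldha were not. Limma called none of the 15, over all genes or adjusted over the list alone, and the list did not pass (median −0.04, camera adjusted p = 0.674). In the simulation limma recovered 22.4% of 1.5-fold changes, so small changes are not excluded. Hif1a (−0.22 ± 0.16), Slc2a1 (−0.03 ± 0.20) and Pdk1 (0.05 ± 0.13) did not pass. Nor did the immediate early genes Fos (−0.23 ± 0.29), Egr1 (0.39 ± 0.35) and Dusp1 (0.32 ± 0.30).

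Genes higher in WT physioxia included Endog, a mitochondrial nuclease (3.51 ± 0.79, adjusted p = 0.0186), Msl3l2 (3.41 ± 0.63, adjusted p = 0.00964), and Glrx5, which serves iron-sulfur cluster assembly (3.29 ± 0.88, adjusted p = 0.039). Zfp622 (3.23 ± 0.50), Ypel3 (3.09 ± 0.57) and Sap30, a subunit of a histone deacetylase complex (3.00 ± 0.49), followed. Lower in WT physioxia were Rn7sk, the noncoding RNA that holds back transcription elongation (−2.24 ± 0.60, adjusted p = 0.0397), the nuclear import receptor gene Tnpo2 (−1.69 ± 0.32), Gdf11 of the TGF-beta family (−1.34 ± 0.30), the interferon-induced GTPase gene Irgm1 (−1.22 ± 0.26), the Notch inhibitor gene Numb (−1.20 ± 0.30), Map3k1 (−1.17 ± 0.30) and Tmppe (−1.11 ± 0.23). Rab5if, Msl3l2, Eif3b, Zfp622, Ypel3, Sap30, Mir17hg, Tnpo2 and Tmppe passed in each fit that left out 1 library, although Tnpo2 and Tmppe did not pass in a fit of the WT libraries alone (adjusted p = 0.0555 and adjusted p = 0.0706). Irgm1 (adjusted p = 0.0695), Numb (adjusted p = 0.0859) and Map3k1 (adjusted p = 0.132) did not pass in that fit either, and Rn7sk did not with array weights (adjusted p = 0.136) or edgeR (adjusted p = 0.0642). Fits that left out 1 library also ended the calls of the others, with the largest adjusted p without WT physioxia 2 for Endog (adjusted p = 0.0661), Glrx5 (adjusted p = 0.139), Rn7sk (adjusted p = 0.139) and Gdf11 (adjusted p = 0.0531), without WT physioxia 1 for Irgm1 (adjusted p = 0.0542), and without WT air 4 for Numb (adjusted p = 0.0975). Map3k1 had its largest without WT air 4 as well (adjusted p = 0.0932).

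Single members of the lists differed between WT physioxia and air without a call for any list (adjusted p = 0.971 with an estimated correlation for each). As above, oxygen and a batch along the sample numbers cannot be told apart for these genes. Of 12 self-renewal regulators, 3 rose in physioxia, the same 3 adjusted over the list alone: the polycomb methyltransferase gene Ezh2 (0.80 ± 0.15, adjusted p = 0.00964), Myb (0.70 ± 0.15) and Lmo2 (1.20 ± 0.28). Of 17 antioxidant genes, 2 rose by either adjustment, the thioredoxin and glutathione reductase genes Txnrd1 (0.73 ± 0.18) and Gsr (1.10 ± 0.27). Of 18 p53 targets, 2 rose by either adjustment, Ei24 (1.19 ± 0.26) and the proapoptotic gene Bbc3 (1.97 ± 0.51). Of 16 megakaryocyte and platelet genes, 2 rose by either adjustment, Rap1b (1.08 ± 0.27) and Gp5 (2.08 ± 0.58). Of 13 neutrophil markers, 1 rose over all genes and 2 adjusted over the list alone, with Camp at 1.57 ± 0.40 (median 0.58, camera adjusted p = 0.0527). With the replicate number as a block the neutrophil list passed (adjusted p = 0.00537). Of 6 stromal and endothelial markers, 1 rose by either adjustment, Plvap (1.39 ± 0.39). Plvap had an adjusted p of 0.0456, and 0.153 without WT air 4. Of 23 long-term stem cell genes, 1 rose by either adjustment, Cdkn1c, which encodes a cell cycle inhibitor (2.79 ± 0.62). Of 14 cytokine and JAK/STAT genes, 1 rose by either adjustment, the cytokine gene Tgfb1 (1.52 ± 0.42), which did not pass with edgeR (adjusted p = 0.0675), after quantile normalization (adjusted p = 0.0546) or without WT air 4 (adjusted p = 0.151). Of 10 genes of DNA methylation and oxygen-dependent dioxygenases, none passed over all genes, and adjusted over the list alone 2 rose and 2 fell, the histone demethylase genes Kdm5b (0.61 ± 0.19) and Kdm4b (0.87 ± 0.32) and the HIF inhibitor gene Hif1an (−0.39 ± 0.12) and Tet1 (−0.52 ± 0.19). Over all genes Kdm5b passed with the replicate number as a block (adjusted p = 0.0257), DESeq2 (adjusted p = 0.0361) and array weights (adjusted p = 0.00191). Hif1an passed with DESeq2 (adjusted p = 0.0321), array weights (adjusted p = 0.0277) and quantile normalization (adjusted p = 0.0284), and Kdm4b (adjusted p = 0.00358) and Tet1 (adjusted p = 0.0336) with array weights. In a fit of the WT libraries alone Lmo2 (adjusted p = 0.0847), Rap1b (adjusted p = 0.111), Plvap (adjusted p = 0.111) and Cdkn1c (adjusted p = 0.0642) did not pass. Plvap did not pass with edgeR (adjusted p = 0.0621) or after quantile normalization (adjusted p = 0.0513) either, nor Gp5 with a pseudocount of 10 (adjusted p = 0.0554). Ezh2 passed in each fit that left out 1 library, Myb did not without WT air 2 (adjusted p = 0.0543), and the largest adjusted p of the others was 0.0673 for Lmo2 without WT physioxia 2, 0.0808 for Txnrd1 without WT physioxia 1, 0.0944 for Gsr, 0.0558 for Ei24, 0.145 for Gp5 without WT physioxia 2, 0.104 for Bbc3 and 0.0831 for Rap1b without WT physioxia 1, 0.109 for Camp and 0.0607 for Cdkn1c without WT air 4.

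For physioxia in WT, limma called 300 genes higher and 52 lower, 352 in all, and 462 with the replicate number as a block, edgeR 334 and DESeq2 529. The count was 0 with annotated genes outside the table counted as unchanged (unadjusted p under 0.05 for 1189 genes, edgeR 0, DESeq2 288) and 96 when these were protein-coding genes alone. It was 152 without WT air 2, 128 without WT air 4, 128, 165, 227 and 554 without WT physioxia 1, 2, 3 and 4.

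In Tet2-deficient cells, no gene passed between physioxia and air. Among the genes with the smallest p were Vac14 (0.59 ± 0.13, adjusted p = 0.353) and Mpp7 (0.72 ± 0.17), with positive differences, and, with negative ones, Sgk1, a stress-responsive kinase (−1.04 ± 0.20, adjusted p = 0.194), Hps6 (−0.79 ± 0.19) and Sertad1 (−0.63 ± 0.16). Eif3b stood at 28042 ± 1009 in physioxia and 11822 ± 11280 in air (2.07 ± 0.64, adjusted p = 0.748), with air libraries at 2179, 1934, 21866 and 21308. The replication-dependent histone list passed with a negative median and no member called, over all genes or adjusted over the list alone (median −0.22, camera adjusted p = 0.0268, adjusted p = 0.916 with an estimated correlation), Hist1h4i (−0.30 ± 0.19) and Hist1h1a (−0.37 ± 0.24) having the smallest p. Limma called 0 genes, with 280 at an unadjusted p under 0.05 where chance gives 305.5, edgeR called 0 and DESeq2 9, among them Vac14, Mpp7 and Sgk1. Without Tet2-deficient air 4 limma called 1 gene.

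The oxygen effect was compared between the genotypes by their interaction. The genes with the smallest p were Spen (1.17 ± 0.29), Slfn9 (0.80 ± 0.22), Inpp5f (0.66 ± 0.19), Tmppe (1.10 ± 0.32) and Vps8 (0.61 ± 0.19), with a higher physioxia effect in Tet2-deficient cells. In the other direction lay Edem1, which serves degradation of misfolded glycoproteins (−1.99 ± 0.46), the polycomb gene Pcgf6 (−1.93 ± 0.49), Rab5if (−3.14 ± 0.82), Kctd5 (−1.12 ± 0.30) and Plekhf2 (−1.10 ± 0.30). None passed (smallest adjusted p = 0.552), so no gene was shown to respond differently in the genotypes. Limma called 0 genes, with 546 at an unadjusted p under 0.05, edgeR called 0 and DESeq2 10, Edem1 and Pcgf6 among them. Without WT air 3 limma called 1 gene, Kctd5. No list passed (smallest adjusted p = 0.492).

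Of the 352 genes called in WT, 299 (84.9%) had the same sign of difference in Tet2-deficient cells, against 51.5% of all genes. The median was 1.40 in WT and 0.40 in Tet2-deficient cells for the genes that rose in WT, and −0.89 and −0.24 for those that fell. These genes were chosen for passing in WT, which enlarges the WT values, so the medians do not show a smaller response in Tet2-deficient cells. Across all genes the oxygen effects of the genotypes had Pearson r = 0.258 and Spearman rho = 0.104, with Pearson r from 0.102 without Tet2-deficient air 1 to 0.379 without Tet2-deficient air 4. On the mean signed log2 level of these 352 genes, set to 0 at the WT air mean, Tet2-deficient air libraries 1 to 4 lay at 0.458, 0.411, 1.32 and 1.56, and Tet2-deficient physioxia libraries between 1.30 and 1.46. The mean difference of 0.432 between these groups (0.935 ± 0.587 and 1.37 ± 0.076, SD, n = 4) did not pass an exact two-sided permutation test (p = 0.371, 70 relabellings). Averaged over genotypes, limma called 209 genes higher and 31 lower in physioxia, 240 in all, 271 with the replicate number as a block and 6 with annotated genes outside the table counted as unchanged. Without WT air 4 it called 139, without Tet2-deficient air 1 141, without WT physioxia 1 147, and without Tet2-deficient physioxia 1, 3 or 4 151, 143 and 156. In that average the neutrophil markers passed (median 0.50, camera adjusted p = 0.0149, adjusted p = 0.995 with an estimated correlation), with 1 of 13 higher by either adjustment.

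**Figure D2:**
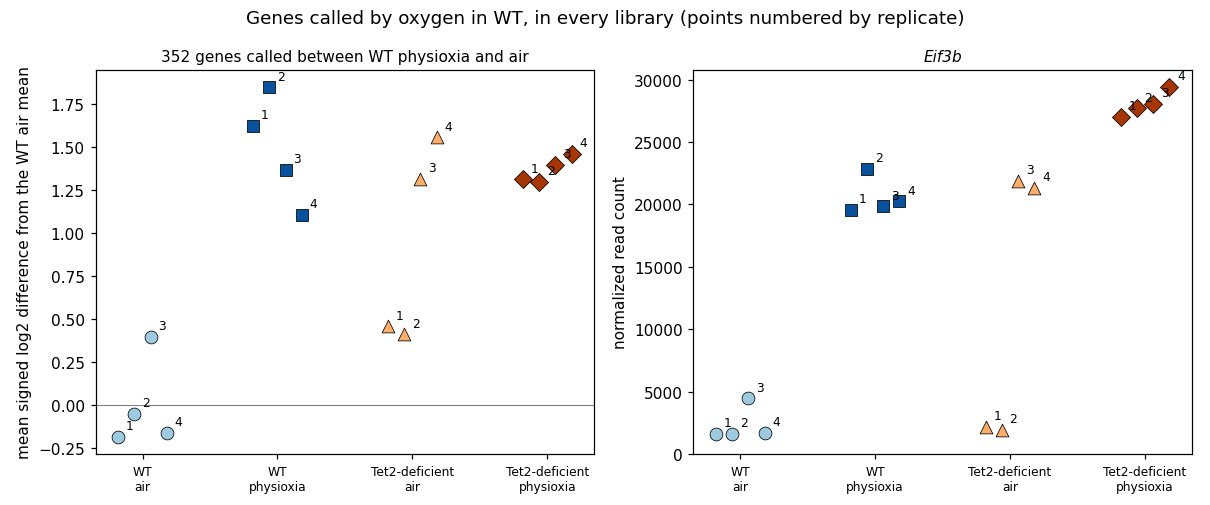
Left, the mean signed log2 level of the 352 genes called between WT physioxia and WT air, relative to the WT air mean, and right, the normalized count of Eif3b, 1 point per library. Tet2-deficient air libraries 3 and 4 lay at 1.32 and 1.56, within the range of the physioxia libraries.

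Whether WT cells kept in physioxia move the way Tet2-deficient cells differ in air was tested on the genes of both comparisons. Of 300 genes higher in WT physioxia, 198 were also higher in Tet2-deficient air libraries, against 126 for independent calls, a number that leaves out of account the shared WT air libraries and how the table's genes were chosen. Of these 300 genes, 269 lay in 1 run of the table, in which 99.38% of the tested genes were higher in Tet2-deficient air libraries, called or not. Edem1 (2.38 ± 0.33 and 1.60 ± 0.33), Pcgf6 (1.94 ± 0.35 and 1.80 ± 0.35) and Rab5if (3.61 ± 0.58 and 2.59 ± 0.58) were higher in both. Of 52 genes lower in WT physioxia, 15 were lower in both, Map3k1 (−1.17 ± 0.30 and −1.36 ± 0.30) and Rn7sk (−2.24 ± 0.60 and −2.00 ± 0.60) among them, against 19.4 for independent calls. Across genes the log2 differences had Pearson r = 0.278, Spearman rho = 0.272 and covariance 0.220. Since both comparisons share the WT air libraries, unchanged groups gave r = 0.494 on average (0.078 to 0.794 in 100 draws), so a positive r alone is no evidence of likeness. The draws held no genotype or oxygen difference, which alters the spread that r is scaled by. Their r thus sets no level for the measured one. Their covariance was 0.0632 ± 0.0302 (SD), below the measured one by 0.156, but the draws did not imitate how the table's genes were chosen. With the WT air libraries split so that none was shared, r was 0.194 (0.131 to 0.258 over 6 splits). The sign was the same in 55.8% of genes, against 66.6% in the draws, which decides nothing, since the draws held no such differences. With unshared controls r was 0.0957, 0.108, 0.233 and 0.287 for Tet2-deficient air libraries 1 to 4 taken singly, so libraries 3 and 4 carried more of it.

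**Figure D3:**
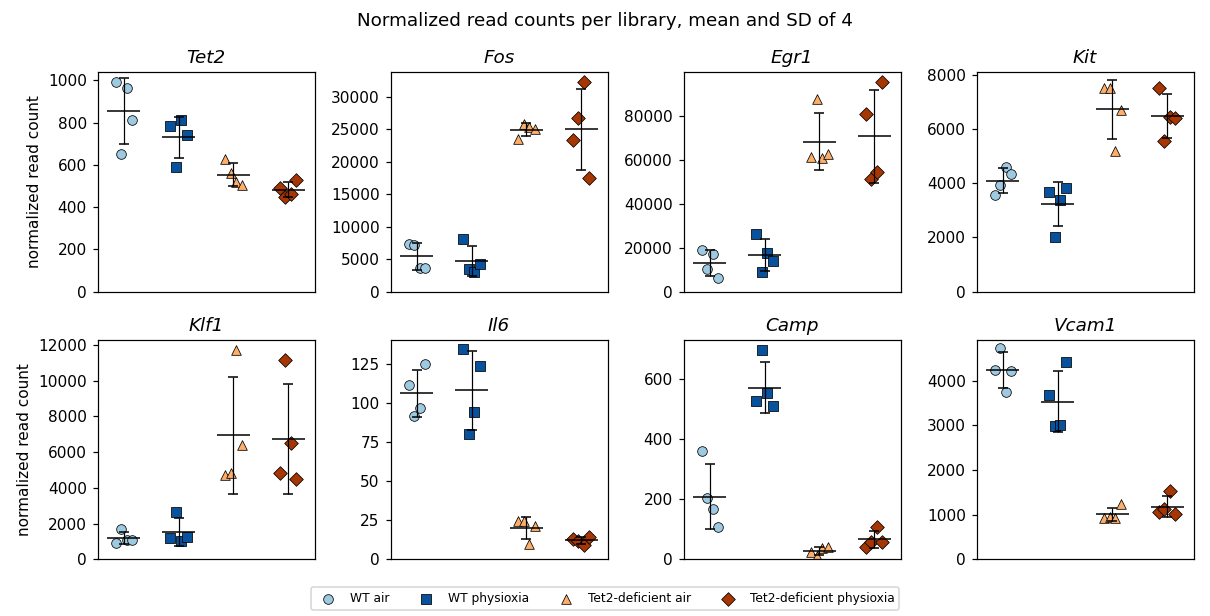
Normalized counts of Tet2, Fos, Egr1, Kit, Klf1, Il6, Camp and Vcam1 in each library by group, with the group mean and SD (n = 4 each). Fos stood at 5430 in WT air and 24887 in Tet2-deficient air, and Il6 at 106 and 20.

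On the table's genes, the main axis between samples was genotype. These genes were already chosen for a difference between groups, so the shares of variance below do not describe the transcriptome. The first component of the 1000 most variable genes held 69.5% of their variance and separated WT from Tet2-deficient libraries. On the second, with 7.10%, WT air libraries lay at 11.2 to 18.8 and WT physioxia libraries at −31.8 to −1.86. Tet2-deficient air libraries 1 and 2 lay at 15.1 and 16.9, libraries 3 and 4 at −7.27 and −9.15, and Tet2-deficient physioxia libraries at −5.42 to 1.24. The labels give no preparation or sequencing batch, so no within-batch value could be had.

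**Figure D4:**
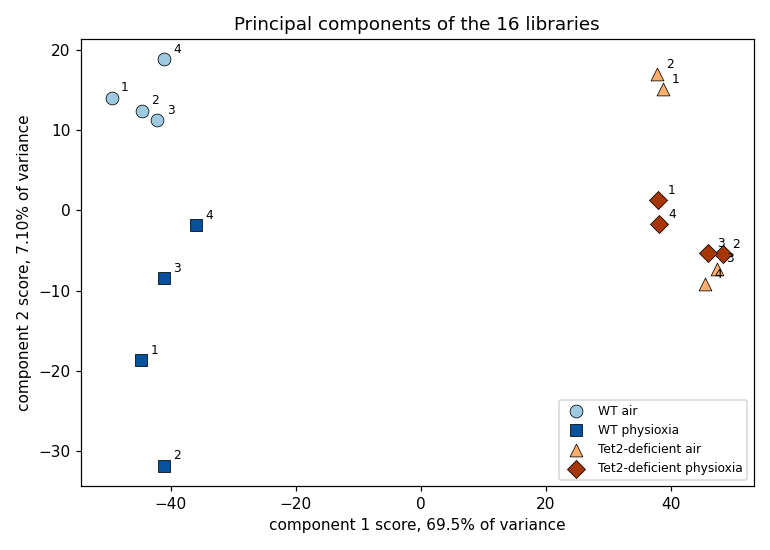
The first and second principal components of the 1000 most variable genes, 1 point per library, with the share of variance of each (69.5% and 7.10%). WT and Tet2-deficient libraries separate on the first, and Tet2-deficient air libraries 3 and 4 lie with the physioxia libraries on the second.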

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

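Of the tests of explanations below, the erythroid carry-over test and the counts over other groupings were chosen before the results they bear on were seen, and the others after.

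Eif3b, the initiation factor gene, stood in Tet2-deficient air replicates 3 and 4 near its physioxia level, and so did the mean of the 352 genes called between WT physioxia and WT air. If oxygen acted alike in both genotypes, each Tet2-deficient air library should lie below each physioxia library; the highest air library lay 0.258 above the lowest physioxia library in mean signed log2, but single libraries of the pattern itself do not exclude it. If oxygen moved these genes, exchanged labels would put as many Tet2-deficient physioxia libraries low as air libraries high. The lowest physioxia library lay at 1.298, which argues against an exchange under that assumption alone. If a batch moved the genes instead, this level would not bear on the labels, so exchanged labels are not excluded. For a preparation or sequencing batch along the sample numbers, the lowest library after the break between numbers 44 and 45 lay 0.647 above the highest of the 6 before it, but the break was placed on these values and the genes were chosen between WT air, all before it, and WT physioxia, all after it, so this gap does not support a batch. The labels give no batch, so oxygen and a batch cannot be told apart here.

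At both oxygen levels, 95 genes with a mean of at least 50 lay at least 8-fold apart between the genotypes, among them Gbp2b, Atp6v0e2 and Baiap3. Pseudogenes were higher in Tet2-deficient libraries in 25 of 26 cases and protein-coding genes in 22 of 41 (two-sided Fisher exact p = 0.000224), and immunoglobulin segments were lower in 20 of 23. Since this test was run on the genes that prompted it, strain variants read on near-identical copies stay open, and all mice are labelled as the same strain. A stretch of chromosome linked to Tet2 is excluded as the whole account, since 93 of these genes lay more than 20 Mb from it. The other 2, Gbp2b among them, lay within 20 Mb of Tet2, so linkage is not excluded for them. Vcam1, named above, also lay within 20 Mb of Tet2. No biological explanation other than the Tet2 label was tested.

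Cell type lists lay apart between the genotypes, erythroid genes higher and neutrophil markers lower. If a smaller share of other cell types lowered all lineage lists alike, the erythroid and neutrophil medians would have the same sign. The erythroid median lay 4.177 above the neutrophil median in air, with the opposite sign, so the lists did not all fall alike. Shares are relative, so fewer cells of 1 type can raise the share of others. A change in the share of other cell types is therefore not excluded. Globin-rich erythroid cells carried over would raise the list in those libraries alone whose globin lay above the WT range. The lowest Tet2-deficient library lay 0.671 above the highest WT library in mean log2 of 22 erythroid genes without globins. This argues against globin-rich cells as the whole cause. Erythroid progenitors with little globin are not covered by this test, so their carry-over stays open. The globin Hbb-bs stood within the WT range, whose highest value was 4553, in 5 of 8 Tet2-deficient libraries and at 31750, 20332 and 6240 in air 3, physioxia 2 and air 4. A shift in progenitor makeup with the genotype was not tested.

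Counts over other groupings of the same libraries were set beside the real ones. For 99.97% of the table's genes an unadjusted DESeq2 p was under 0.05 in at least 1 of the 4 real comparisons. The real grouping was thus favoured in advance, so its higher counts, drawn splits included, do not measure chance. The real grouping gave 352 genes for physioxia in WT against at most 92 in the other of 35 splits (1 of 35 reached its count), 4858 against 69 for the genotypes in air (1 of 35) and 4243 against 241 in physioxia (1 of 35). The split that gave 92 set WT replicates 1 and 2 of both conditions against 3 and 4, and the splits ignored any pairing of replicates. For physioxia in Tet2-deficient cells the real grouping gave 0, which any split reaches (35 of 35), so this count decides nothing, and the highest other split gave 305. That split set air 1 and 2 and physioxia 1 and 4 against the rest, whose erythroid levels were 11.1 to 11.3 and 11.8 to 12.7. For the 0 genes of the interaction the 100 of 100 drawn splits decide nothing either (highest other 388). Of 100 drawn splits, 2 reached the 240 of physioxia averaged over genotypes (283) and 1 the 5449 of the averaged genotype difference (3863).

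In groups of 4 libraries, 1 value stood far from the other 3 by Dixon's ratio at the 95% level in 53 of 746 groups tested (7.1%), where chance gives about 1 in 20. Of these, 6 were a value above 0 against 3 zeros, where the ratio is 1 by construction, which leaves 47 of 740 groups (6.35%). The total of normalized counts was 14465000 in WT physioxia replicate 2, against 11980000 to 12220000 in the other 3. In WT air the genes were Birc3 (2856, low, replicate 2, others 3693 to 3782), Cxcl10 (3304, high, replicate 1, others 1863 to 2090), Hk3 (9051, low, replicate 3, others 12340 to 12870), Gbp2b (0.957, high, replicate 4, others 0), Atp6v0e2 (2.01, high, replicate 2, others 0), Cd83 (7730, high, replicate 1, others 5931 to 6173), Eif3b (4469, high, replicate 3, others 1624 to 1683), Rab5if (747, high, replicate 3, others 180 to 233), Msl3l2 (74.9, high, replicate 3, others 18.1 to 20.2), Ypel3 (860, high, replicate 3, others 158 to 274), Sap30 (1618, high, replicate 3, others 330 to 475) and Rpl24 (26.4, high, replicate 3, others 17.3 to 18.2). In WT air the lists, as mean log2 levels, were DNA methylation and oxygen-dependent dioxygenases (10.5, high, replicate 3, others 10.1 to 10.2). In Tet2-deficient air the genes were Vcam1 (1230, high, replicate 4, others 923 to 952), Egr1 (87495, high, replicate 2, others 60990 to 62680), Myc (14527, low, replicate 4, others 15320 to 15350), Cxcl10 (757, high, replicate 3, others 545 to 563), Gfi1b (3457, high, replicate 3, others 2443 to 2547), Car2 (146670, high, replicate 3, others 72620 to 80370), Baiap3 (0.846, high, replicate 4, others 0), Cdkn1c (38.1, high, replicate 4, others 8.68 to 13.0), Sgk1 (458, high, replicate 1, others 340 to 349), Hbb-bs (31750, high, replicate 3, others 1709 to 6240), Me1 (44.3, high, replicate 2, others 26.0 to 28.8) and Tdg (1066, low, replicate 4, others 1161 to 1180). In Tet2-deficient air the lists, as mean log2 levels, were nuclear oxidative phosphorylation (11.6, low, replicate 2, others 12.0 to 12.1) and cytokine and JAK/STAT signalling (10.4, low, replicate 2, others 10.5). In WT physioxia the genes were Klf1 (2672, high, replicate 2, others 1005 to 1244), Pdzk1ip1 (550, high, replicate 2, others 360 to 384), Fcgr3 (20254, high, replicate 2, others 11990 to 13220), Pfkp (1660, low, replicate 2, others 2413 to 2568), Gbp2b (1.71, high, replicate 4, others 0), Ncs1 (427, low, replicate 1, others 679 to 722), Nr4a1 (38690, high, replicate 1, others 25070 to 27380), Exo1 (502, high, replicate 4, others 406 to 416), Hspa8 (158460, high, replicate 2, others 104800 to 113600), Cdkn1c (90.4, high, replicate 2, others 13.7 to 24.8), Kdm4b (461, low, replicate 2, others 944 to 1026), Spen (125, low, replicate 2, others 238 to 261), Rpl24 (21.4, high, replicate 3, others 14.5 to 15.3), Pmaip1 (12341, low, replicate 4, others 16810 to 17150) and Csf2ra (5919, high, replicate 1, others 4935 to 5102). In WT physioxia the lists, as mean log2 levels, were AP-1 and immediate early genes (12.0, high, replicate 1, others 11.4 to 11.5) and antioxidant and NRF2 targets (10.5, high, replicate 2, others 9.87 to 9.96). In Tet2-deficient physioxia the genes were Btg2 (10469, low, replicate 4, others 13200 to 13490), Il5ra (56.2, low, replicate 2, others 63.8 to 65.3), Cd3e (12.2, low, replicate 3, others 12.9 to 13.0), AC102496.1 (3.54, high, replicate 1, others 0), Baiap3 (3.44, high, replicate 4, others 0) and Hbb-bs (20332, high, replicate 2, others 2118 to 4065). In Tet2-deficient physioxia the lists, as mean log2 levels, were lymphoid priming (9.54, low, replicate 3, others 9.79 to 9.82) and mature neutrophil markers (7.68, high, replicate 3, others 7.04 to 7.12).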

How the results depend on the processing

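Counts stayed within 1.5 times in 30 of 33 other fits for the genotypes in air, 30 of 32 in physioxia, 21 of 31 for physioxia in WT and 20 of 30 for physioxia averaged over genotypes. For physioxia in WT (352 genes) array weights gave 782, DESeq2 529, all annotated genes 0 and protein-coding genes 96, and leaving out 1 library 128 to 554. In Tet2-deficient cells (0) a pseudocount of 10 and array weights gave 1 each and DESeq2 9, and leaving out 1 library 0 to 1. Averaged over genotypes (240) array weights gave 525, a log2 difference of at least 1 116, all annotated genes 6, protein-coding genes 97, and leaving out 1 library 139 to 359. For the interaction (0) DESeq2 gave 10 and leaving out 1 library 0 to 1. For the genotypes a log2 difference of at least 1 gave 1976 in air (4858), 1689 in physioxia (4243) and 1821 averaged (5449), and all annotated genes 2432 in air and 2477 in physioxia. Without Tet2-deficient air 3 and 4, air gave 2760. Leaving out 1 library gave 4050 to 5274, 3842 to 4306 and 5290 to 5630. The bounds over more genes and the size limit lower counts by construction. For the others the cause was not tested.

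Lists called for physioxia in WT (0) came to 1 with the replicate block and 1 after quantile normalization, and in Tet2-deficient cells (1) to 0 with an estimated correlation and 0 with fry. For the genotype they came to 0 with an estimated correlation in air (15) and in physioxia (15), and to 24 with fry in physioxia, and the cause was not tested. Without 1 library, Tet2 lay at −0.74 to −0.53 in air and −0.69 to −0.54 in physioxia and passed in each fit. The Pearson r of physioxia in WT with Tet2 deficiency in air lay at 0.231 to 0.312, and that of the oxygen effects of both genotypes at 0.102 to 0.379. No named gene or list past its threshold changed sign, but 73 and 24 values of them below it did, and after quantile normalization more genes were lower than higher in air (1984 and 2303) and physioxia (1909 and 1938). Of the other values, list tests stayed the same in 756 cases, weakened in 39, strengthened in 21 and moved in 24, and named genes in 15592, 164, 77 and 73. Depth of 7.77 to 15.7 M reads limits genes with few reads.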

Other observations

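The look at the order of genes in the table and the fits without Tet2-deficient air 3 and 4 were chosen after results were seen, and the other tests before.

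The remaining gene lists did not pass camera between the genotypes in air, and apart from dendritic cell markers did not pass in physioxia, while single members of most lists did (limma, n = 4 per group; log2 difference ± SE in air and physioxia). By fry, lists that passed in air were lymphoid priming (adjusted p = 0.00172), stromal (adjusted p = 2.62e-05), cholesterol synthesis (adjusted p = 0.00187), cytokine (adjusted p = 0.0289), B cell (adjusted p = 0.00187) and dendritic cell (adjusted p = 0.0495), all at an adjusted p = 0.44 or more by camera with an estimated correlation. In physioxia they were p53 targets (adjusted p = 0.0109), lymphoid priming (adjusted p = 0.000472), stromal (adjusted p = 8.01e-05), ribosomal protein (adjusted p = 0.00788), cholesterol synthesis (adjusted p = 0.00746), B cell (adjusted p = 8.01e-05) and megakaryocyte (adjusted p = 0.0215), all at an adjusted p = 0.426 or more by camera with an estimated correlation. Among antioxidant genes, of 17 measured in air 9 were higher and 5 lower, with the same numbers adjusted over the list alone (median 0.51, camera adjusted p = 0.525), and in physioxia 5 were higher and 6 lower, with the same numbers adjusted over the list alone (median 0.11, camera adjusted p = 0.902). They held the malic enzyme gene Me1 (3.20 ± 0.60 and 2.90 ± 0.60), higher, and the cystine transporter gene Slc7a11 (−1.54 ± 0.29 and −1.59 ± 0.29), lower. Among p53 targets, of 18 measured in air 9 were higher and 7 lower, with the same numbers adjusted over the list alone (median 0.31, camera adjusted p = 0.763), and in physioxia 6 were higher and 8 lower, with the same numbers adjusted over the list alone (median −0.45, camera adjusted p = 0.529). The proapoptotic gene Pmaip1 (−2.29 ± 0.24 and −2.01 ± 0.24) and the death receptor gene Fas (−1.73 ± 0.22 and −1.65 ± 0.22) were lower. Among cytokine and JAK/STAT genes, of 14 measured in air 5 were higher and 7 lower, with the same numbers adjusted over the list alone (median −0.16, camera adjusted p = 0.351), and in physioxia 4 were higher and 6 lower, with the same numbers adjusted over the list alone (median −0.08, camera adjusted p = 0.51). The receptor genes Csf2ra (−1.33 ± 0.11 and −1.09 ± 0.11) and Ifngr1 (−0.64 ± 0.10 and −0.48 ± 0.10) were lower, Ifngr1 not past the threshold in physioxia after quantile normalization (adjusted p = 0.066). Among genes of DNA methylation and oxygen-dependent dioxygenases, of 10 measured in air 4 were higher and 4 lower (4 and 5 adjusted over the list alone) (median −0.12, camera adjusted p = 0.763), and in physioxia 3 were higher and 3 lower, with the same numbers adjusted over the list alone (median 0.07, camera adjusted p = 0.905). Tdg, the glycosylase that removes oxidised methylcytosine, was lower (−0.77 ± 0.11 and −0.78 ± 0.11). Among cholesterol synthesis genes, of 6 measured in air 1 was higher and 5 lower, with the same numbers adjusted over the list alone (median −0.79, camera adjusted p = 0.0613), and in physioxia 1 was higher and 5 lower, with the same numbers adjusted over the list alone (median −0.65, camera adjusted p = 0.118). Mvd (−1.08 ± 0.18 and −0.80 ± 0.18) was lower.

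Among lymphoid priming genes, of 14 measured in air 4 were higher and 8 lower, with the same numbers adjusted over the list alone (median −0.57, camera adjusted p = 0.15), and in physioxia 2 were higher and 8 lower, with the same numbers adjusted over the list alone (median −0.56, camera adjusted p = 0.0929). Ighm (−1.35 ± 0.14 and −1.35 ± 0.14) and the chemokine receptor gene Ccr9 (−1.75 ± 0.38 and −1.80 ± 0.38) were lower. Among B cell markers, of 11 measured in air 3 were higher and 6 lower, with the same numbers adjusted over the list alone (median −0.57, camera adjusted p = 0.298), and in physioxia 0 were higher and 6 lower (0 and 5 adjusted over the list alone) (median −0.88, camera adjusted p = 0.0929), with Iglc2 (−2.44 ± 0.30 and −2.10 ± 0.30) lower. Among dendritic cell markers in air, of 15, 2 were higher and 8 lower, with the same numbers adjusted over the list alone (median −0.81, camera adjusted p = 0.0786), with Bst2 (−0.74 ± 0.12 and −0.93 ± 0.12) lower. Among megakaryocyte and platelet genes, of 16 measured in air 6 were higher and 6 lower, with the same numbers adjusted over the list alone (median −0.48, camera adjusted p = 0.738), and in physioxia 3 were higher and 8 lower, with the same numbers adjusted over the list alone (median −0.79, camera adjusted p = 0.244). Plek (−0.80 ± 0.17 and −0.82 ± 0.17) was lower and the platelet adhesion gene Selp (0.95 ± 0.21 and 1.15 ± 0.21) higher. Among stromal and endothelial markers, of 6 measured in air 2 were higher and 3 lower, with the same numbers adjusted over the list alone (median −0.67, camera adjusted p = 0.222), and in physioxia 1 was higher and 3 lower, with the same numbers adjusted over the list alone (median −0.57, camera adjusted p = 0.177), with Spp1 (−2.13 ± 0.21 and −2.09 ± 0.21) and Flt1 (−1.66 ± 0.23 and −1.09 ± 0.23) lower. Among G2/M genes, of 17 measured in air 6 were higher and 8 lower (7 and 9 adjusted over the list alone) (median −0.25, camera adjusted p = 0.351), and in physioxia 4 were higher and 5 lower, with the same numbers adjusted over the list alone (median −0.04, camera adjusted p = 0.729), with Cks2 (−1.01 ± 0.14 and −1.06 ± 0.14) lower. Among nuclear oxidative phosphorylation genes, of 6 measured in air 1 was higher and 1 lower, with the same numbers adjusted over the list alone (median −0.04, camera adjusted p = 0.763), and in physioxia 1 was higher and 3 lower, with the same numbers adjusted over the list alone (median −0.13, camera adjusted p = 0.729), with the cytochrome gene Cycs (−0.61 ± 0.15 and −0.56 ± 0.15) lower. Among mitochondrially encoded genes, of 3 measured in air 2 were higher and 1 lower, with the same numbers adjusted over the list alone (median 0.51, camera adjusted p = 0.738), and in physioxia 2 were higher and 0 lower, with the same numbers adjusted over the list alone (median 0.52, camera adjusted p = 0.488), with mt-Nd1 (0.55 ± 0.18 and 0.52 ± 0.18) higher. Of 63 listed ribosomal protein genes, only 6 were measured. Among these, in air 1 was higher and 2 lower, with the same numbers adjusted over the list alone (median −0.24, camera adjusted p = 0.351), and in physioxia 1 was higher and 4 lower (1 and 5 adjusted over the list alone) (median −0.55, camera adjusted p = 0.133), with Rpl24 (0.81 ± 0.26 and 0.95 ± 0.26) higher. Calls were lost in air for mt-Nd1 (adjusted p = 0.0605) and Rpl24 (adjusted p = 0.145) without Tet2-deficient air 3 and 4, and for Rpl24 after quantile normalization (adjusted p = 0.0874). In physioxia they were lost for Cycs (adjusted p = 0.0548) after quantile normalization, and for mt-Nd1 without WT physioxia 2 (adjusted p = 0.0613) or Tet2-deficient physioxia 3 (adjusted p = 0.0636). The dendritic cell list passed in air with the replicate block (adjusted p = 0.0372), and in physioxia the stromal (adjusted p = 0.0288) and ribosomal protein (adjusted p = 0.0474) lists passed with a minimum count of 50. With an estimated correlation and the minimum of 10 they did not (adjusted p = 0.653, adjusted p = 0.428 and adjusted p = 0.482). Of sex-linked genes, Tsix, an antisense transcript of X inactivation, was higher in Tet2-deficient libraries (3.33 ± 0.52 in air), and Uty, on the Y chromosome, lay at 0.26 ± 0.10 and 0.42 ± 0.10, not past the threshold in air with TMM factors (adjusted p = 0.051), with the replicate block (adjusted p = 0.0505) or after quantile normalization (adjusted p = 0.298), nor without WT air 1 (adjusted p = 0.075) or 2 (adjusted p = 0.0584) or Tet2-deficient air 1 (adjusted p = 0.0894) or 2 (adjusted p = 0.064). The sexes of the mice in each library are not given.

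The 4 runs of ascending identifier in the table differed in direction. The median log2 difference between the genotypes in air was −0.69, 0.81, −0.56 and 0.85 in runs 1 to 4 (1377, 2608, 1478 and 647 tested genes), and that of physioxia in WT −0.21, −0.03, 0.12 and 1.02. Run 4 held 269 of the 300 genes higher in WT physioxia.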
